A study of Mus musculus with 8 samples.

How the data were processed

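Poly-A RNA from the ascending aorta of Fbn1 mgR/mgR mice, a mouse model of Marfan syndrome with low expression of fibrillin-1, was sequenced as paired-end reads on an Illumina NovaSeq, per the labels' protocols. There were 8 libraries, 4 from mice given DT-061 and 4 from mice given the vehicle solution. Reads were handled with HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and the mm10 build, per the submitters' processing notes, which do not say which step each tool made. The deposited values are FPKM (fragments scaled to the gene's length and to the library's mapped fragments) made by the authors, and which total of fragments they used is not given in the sources used here. The counting's strand setting is not given either, so reads of overlapping and antisense genes cannot be told apart.

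The table analysed here held 1329 genes, named by Ensembl identifiers, and its deposited name says that it holds genes significant between the groups. The tool and the threshold behind that choice are not given in the sources used here. The smallest absolute log2 ratio of the group mean FPKM was 0.12 and 589 genes had one under 1, so the choice was not a 2-fold minimum. Because the genes were chosen on the comparison that is tested below, a p-value from these values is not independent evidence, no share of all genes can be given, and no enrichment against the genome was run. Symbols for 1328 genes came from the reference table of gene names, and coordinates, biotypes, exonic lengths and GC content from GENCODE release M21 on GRCm38, the same build as mm10. In that annotation, 1216 of the genes were protein coding, 41 were immunoglobulin variable genes, 3 were immunoglobulin constant genes and the remaining 69 were of other kinds or, for 1 of them, not found in it.

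The depth of each library was recovered from the steps between low FPKM values, since FPKM times exonic length is a whole multiple of what 1 fragment is worth. Multiples up to 60 were used, and a value within 0.03 of a whole number was taken as whole. The step was chosen on genes whose low values were already whole at a first-pass step in at least 3 other libraries. That left 27 to 43 values per library. Of these preselected values, 92.6% to 100% were whole at the step chosen, against 0% to 5.13% at the median step tried. This gave 14100000 to 22200000 fragments per library, to 3 significant digits.

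The main test was limma 3.58.1 with the trend and robust options in R 4.3.3, on log2(FPKM + 1) of the 8 libraries with the treatment as the only term, with Benjamini-Hochberg adjustment over the 1329 genes and a threshold of 0.05. A change is therefore the DT-061 mean minus the vehicle mean of log2(FPKM + 1), which understates the change of genes with low values. In the text, rose and fell are used of genes past that threshold, and fold changes are ratios of the group mean FPKM. The procedure was tested on simulated data for DT-061 against vehicle with 1329 genes, of which 100 were changed by 1 log2 unit, 100 by 2 log2 units and 1129 not at all. It recovered 62.0% and 87.0% of the changed genes and called 0.886% of the unchanged ones. Most simulated genes were unchanged and their noise was independent, whereas 1268 of the 1329 real, selected genes passed. These shares are therefore not the error rates of the calls below.

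There were 36 gene lists (signalling, matrix, metabolism, immune response and markers of other cell types), fixed with the test, the alternatives and the rule for named genes before the data were examined. For each list, the members in the table were counted by direction and outcome, and the score of a list is the mean log2(FPKM + 1) of its members in the table. Lists with at least 5 members in the table were tested by a two-sided Fisher's exact test of higher against lower, compared with all other genes in the table, with adjustment over the 19 lists tested. Because the table was selected, such a test asks whether a list leans more to a side than the table does. Outcomes with limma adjusted over a list alone are given as well. In the table, 1274 of the 1329 genes had an unadjusted limma p under 0.05, so that adjustment could hardly change the counts and adds no support. Genes are not independent replicates, so its p-value is a description and does not measure the spread between libraries. The named genes were Fbn1 and the members of the list of protein phosphatase 2A genes, the 10 largest rises and the 10 largest falls among protein coding genes with a mean FPKM of at least 1 whose groups did not overlap, and up to 4 genes with the largest change and a mean FPKM of at least 1 from each list with at least 3 members in the table. Some genes that this rule picks are not reported here. All other genes named in the text, among them most of those given because a scaling turned their direction, were chosen after their values were seen.

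Alternatives were a pseudocount of 0.1, a minimum mean FPKM of 1, limma without the trend and robust options, limma with array weights, quantile normalization, rescaling of each library to the same median over the genes in the table, the replicate number as a block, an exact permutation test per gene over 70 assignments, and each library left out in turn. The count tests listed as alternatives for count tables were not run, because the deposited values are FPKM, and neither was a competitive gene set test, because the genes were selected. No pair of libraries held identical values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.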

Results

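Gene expression was measured by poly-A RNA sequencing in the ascending aorta of Fbn1 mgR/mgR mice, which have low expression of fibrillin-1, a microfibril protein of the elastic matrix, and serve as a model of Marfan syndrome. Mice received DT-061, an orally active small molecule that activates protein phosphatase 2A (PP2A), or the vehicle solution alone. The dose was 5 mg/kg, given 2 times a day from 5 weeks of age for 4 weeks. The comparison asks how activation of this phosphatase alters the transcripts of the diseased aorta. Each group had 4 libraries, and no label states that each came from a separate mouse. The limma p-values therefore measure the spread between these samples, which may in part be technical. To 3 significant digits, DT-061 libraries 1 to 4 held 14400000, 15600000, 14500000 and 14700000 fragments, and vehicle libraries 1 to 4 held 16200000, 22200000, 17500000 and 14100000.

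Contractile smooth muscle genes were higher in the DT-061 aortas, and genes of immune cells, cytokines, the interferon response, antigen presentation and cell division were lower. All 18 contractile genes in the table rose, among them the myosin light chain gene Myl9, which was 2.02-fold higher. The antigen presentation gene Cd74 was 4.21-fold lower and the chemokine gene Ccl5 was 11.5-fold lower. The Notch target gene Heyl rose by 1.04 ± 0.28 on the log2 scale (SE, n = 4 per group).

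The table analysed had been reduced to 1329 genes significant between the groups, so the counts describe that selection. In it, 435 genes were higher and 894 lower with DT-061, so 67.3% were lower (95% exact binomial interval 64.7% to 69.8%). Genes are not independent replicates, so the interval is a description. By limma, 404 genes rose and 864 fell at an adjusted p under 0.05, and 61 did not pass. The rises were smaller, with a median log2 change of 0.49 against -0.88 for the falls. At least 1 log2 unit was reached by 11 of the genes that rose and by 363 of those that fell. In 1041 genes (78.3%), 400 of them higher and 641 lower, the 4 DT-061 values did not overlap the 4 vehicle values, where chance gives 2.86% of unselected genes. Another scaling moved this balance. With each library rescaled to the same median over the table, which shifted the changes by a median of 0.68, 434 genes rose and 301 fell, so that 59.0% of the calls were rises against 31.9% as deposited. With quantile normalization, which shifted them by a median of 0.56, 394 rose and 209 fell (65.3% rises). Both scalings assume a balance that a table selected in this way need not have.

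**Figure D1:**
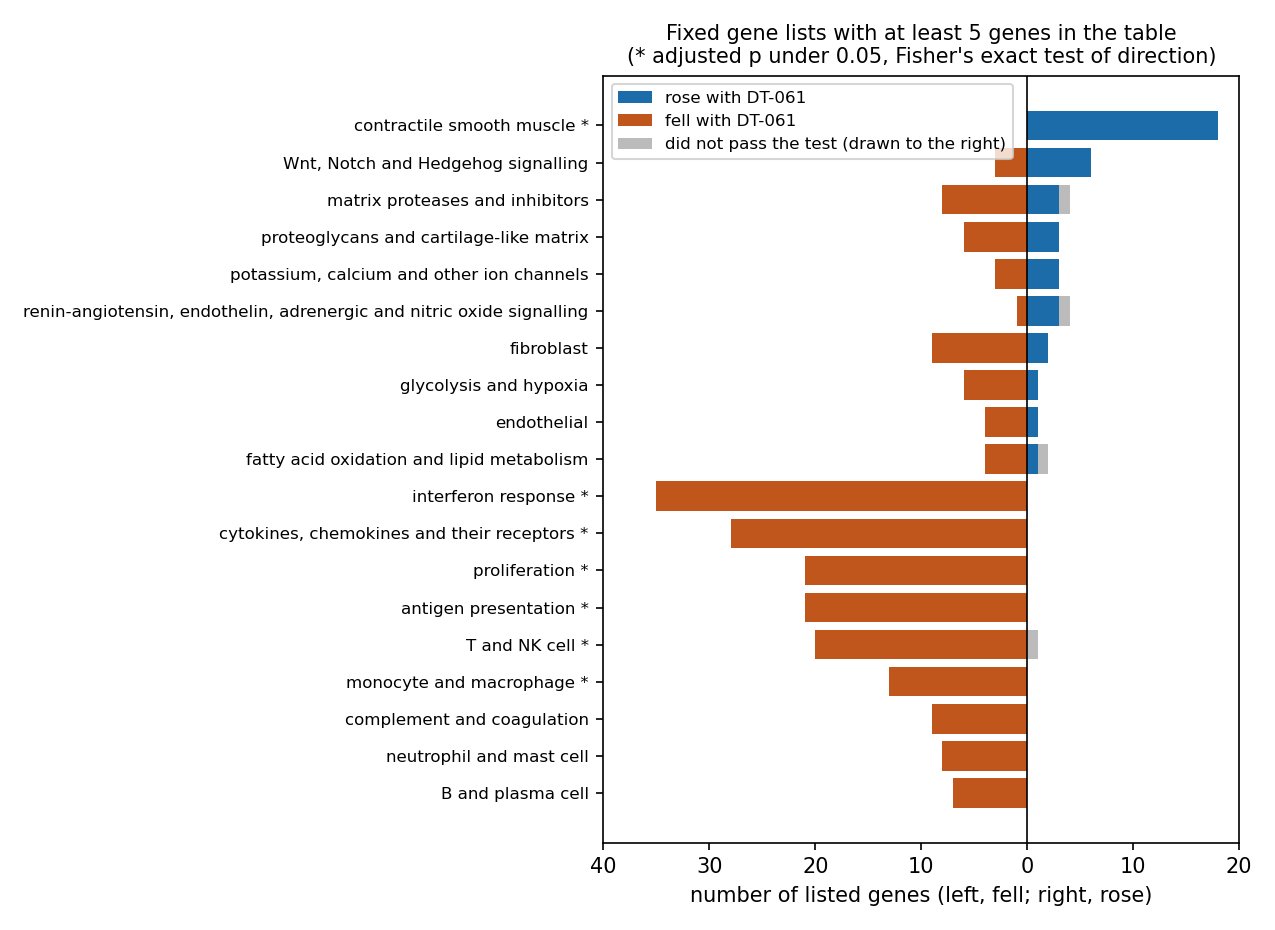
Number of genes of each fixed list that fell (left) or rose (right) with DT-061 by limma, or did not pass the test (grey), for the 19 lists with at least 5 members in the table. The contractile smooth muscle list is the only list past the threshold that leans to rises (18 of 18), and 6 lists past it, marked by asterisks, lean to falls.

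The contractile smooth muscle list, genes of the actin and myosin apparatus of the vessel wall, had 18 of its 39 members in the table. All 18 rose, over all genes tested and adjusted over the list alone, and in all 18 the groups did not overlap (Fisher's exact test of direction, adjusted p = 2.8e-08). Their median log2 change was 0.70. Myh11, the smooth muscle myosin heavy chain (Ensembl ENSMUSG00000018830, GRCm38 chromosome 16, 14194535 to 14291372), had 1052 ± 205 FPKM with DT-061 and 605 ± 93.6 with vehicle (SD, n = 4), a log2 change of 0.79 ± 0.17 (SE; limma adjusted p = 0.016). Myl9 (chromosome 2, 156775420 to 156781658) had 3336 ± 1057 FPKM against 1651 ± 269, a log2 change of 0.98 ± 0.22 (limma adjusted p = 0.016). The calponin gene Cnn1 rose by 0.80 ± 0.19 and the tropomyosin gene Tpm2 by 0.86 ± 0.23 on the log2 scale. The score of the list was 8.78 ± 0.18 with DT-061 and 8.10 ± 0.20 with vehicle (SD, n = 4). DT-061 library 3 had the highest score, 9.03, and vehicle library 1 the lowest, 7.83. With quantile normalization, the actin gene Acta2, not picked by the naming rule, turned to lower and the other 17 contractile genes stayed higher. The size of the rises depended on the scaling. Myh11, Myl9, Cnn1 and Tpm2 changed by 1.64, 1.83, 1.65 and 1.71 with the median rescaling. With quantile normalization they changed by 0.63, 0.74, 0.87 and 0.76.

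**Figure D2:**
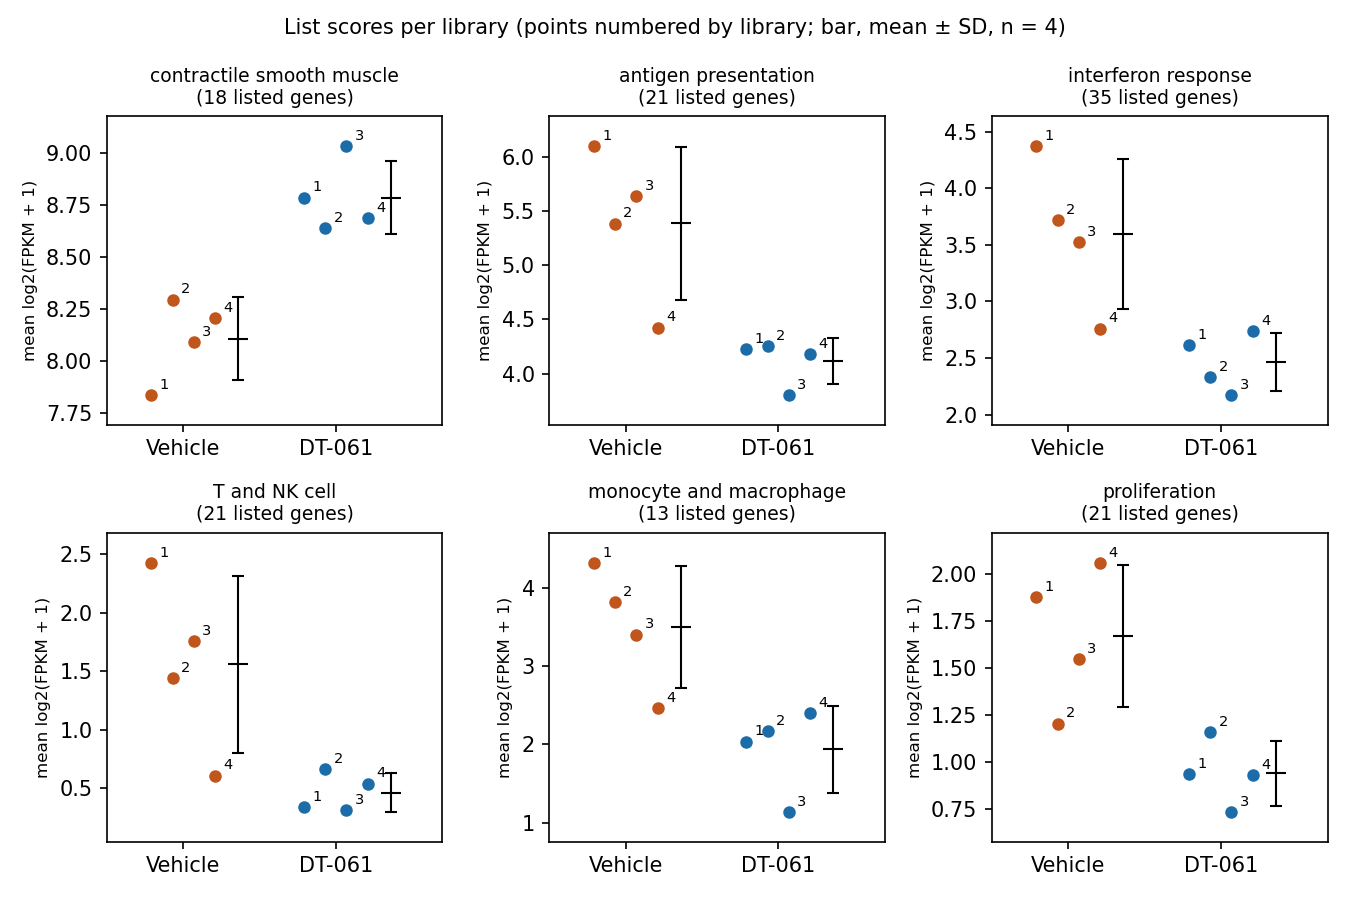
Score (mean log2(FPKM + 1) over the list's genes in the table) of 6 fixed lists in each library, with the library's number beside its point and the mean ± SD (n = 4) beside each group. Vehicle library 4 lies near the DT-061 libraries for antigen presentation (4.43), interferon response (2.76) and T and NK cell genes (0.61), but within the vehicle range for contractile genes (8.20) and at the top for proliferation (2.06).

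Immune cell markers fell across lineages. In the list of T and NK cell markers, 20 of the 21 members in the table fell and 1 did not pass, with the same counts adjusted over the list alone. In 5 of the 21 the groups did not overlap, against 78.3% of all genes in the table. The list leaned to lower values (Fisher's exact test, adjusted p = 8.7e-04). The T cell adhesion gene Cd2 had 0.564 ± 0.277 FPKM with DT-061 and 5.05 ± 5.02 with vehicle (SD, n = 4), a log2 change of -1.65 ± 0.49 (limma adjusted p = 0.019), and lost its call with quantile normalization, at -0.78. All 13 monocyte and macrophage markers fell, as they did adjusted over the list alone (Fisher's exact test, adjusted p = 0.019), among them the pore-forming protein gene Mpeg1 at -2.14 ± 0.64 and Plac8 at -1.96 ± 0.56 on the log2 scale. All 7 B and plasma cell genes and all 8 neutrophil and mast cell genes fell, likewise adjusted over the list alone. These lists did not pass the test of direction (Fisher's exact test, adjusted p = 0.16 and 0.11). Every gene was already lower, so lists of this size could not have passed on the lower side in the table as deposited (Fisher's exact test, unadjusted p = 0.10 and 0.059). The groups did not overlap in 7 of the 13 monocyte and macrophage genes. They did not overlap in 5 of the 7 B and plasma cell and 6 of the 8 neutrophil and mast cell genes. Several single calls here were sensitive to leaving out 1 library, which also leaves fewer values to test. With 1 library left out, Ighm lost its call in 6 of 8 cases (limma adjusted p of 0.055 to 0.10), S100a8 in 6 (0.053 to 0.070) and S100a9 in 7 (0.053 to 0.079), and with quantile normalization all 3 did, as Ighm did with the median rescaling and S100a9 with the pseudocount of 0.1. Among T and NK cell genes, Lck and Trbc2 each lost their call in 3 of 8 cases (0.054, and 0.053 to 0.061) and with quantile normalization. Igha, the constant region of immunoglobulin A, had 7.46 ± 6.25 FPKM with DT-061 and 696 ± 544 with vehicle, a log2 change of -5.83 ± 1.04 (limma adjusted p = 0.013). The joining chain gene Jchain (chromosome 5, 88519809 to 88527891) fell by 4.68 ± 0.99 on the log2 scale (limma adjusted p = 0.016), and its 4 vehicle libraries spread from 5.49 to 235 FPKM. Vehicle library 4 was close to the DT-061 libraries in these groups. Its T and NK cell score was 0.61, against 1.44 to 2.43 in the other vehicle libraries and 0.31 to 0.66 with DT-061, and its B and plasma cell score was 3.42, against 5.04 to 6.90 and 1.60 to 2.78. Immunoglobulin genes share near-identical sequence, so reads may be split between them and their single values are uncertain. With quantile normalization, the T and NK cell genes Cd28, Cd6, Icos and Prf1 and Arg1 were among those that turned to higher, and Sdc1 did so with the median rescaling; these were not picked by the naming rule.

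Cytokine, interferon and antigen presentation genes fell together. All 28 listed cytokine, chemokine and receptor genes fell, also adjusted over the list alone (Fisher's exact test, adjusted p = 1.1e-04). Ccl5 had 1.26 ± 0.629 FPKM with DT-061 and 14.5 ± 8.02 with vehicle (SD, n = 4), a log2 change of -2.62 ± 0.47 (limma adjusted p = 0.013), and the chemokine gene Ccl8 fell by 3.18 ± 0.69 (limma adjusted p = 0.016). All 35 interferon response genes fell, also adjusted over the list alone (Fisher's exact test, adjusted p = 1.1e-05). The interferon-inducible gene Ifi27l2a had 90.7 ± 26.7 against 266 ± 104 FPKM and was 2.93-fold lower, and Irf7, a transcription factor of that response, fell by 1.77 ± 0.50. All 21 antigen presentation genes fell, also adjusted over the list alone (Fisher's exact test, adjusted p = 8.7e-04). The groups did not overlap in 16 of the 28 cytokine, 19 of the 35 interferon response and 15 of the 21 antigen presentation genes. The share over the whole table was 78.3%. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 were 4.69-fold, 4.82-fold and 4.84-fold lower, and Cd74 (chromosome 18, 60803848 to 60812652), their invariant chain, had 190 ± 59.6 against 800 ± 420 FPKM, with a log2 change of -1.92 ± 0.50 (limma adjusted p = 0.018). In vehicle library 4, Cd74 stood at 256 FPKM, against 704 to 1218 in the other vehicle libraries, and DT-061 library 3 had the lowest value, 103. The library's interferon score was 2.76 against 3.52 to 4.37 in the other vehicle libraries and 2.17 to 2.74 with DT-061. With the median rescaling, Gbp7, Irf1, H2-T22 and Tap2 turned to higher, and with quantile normalization Ccl11, Ptges, Tnf, Gbp4 and Mx2 did, all chosen after their values were seen. H2 genes resemble each other closely, so their single values are uncertain where reads were split.

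**Figure D3:**
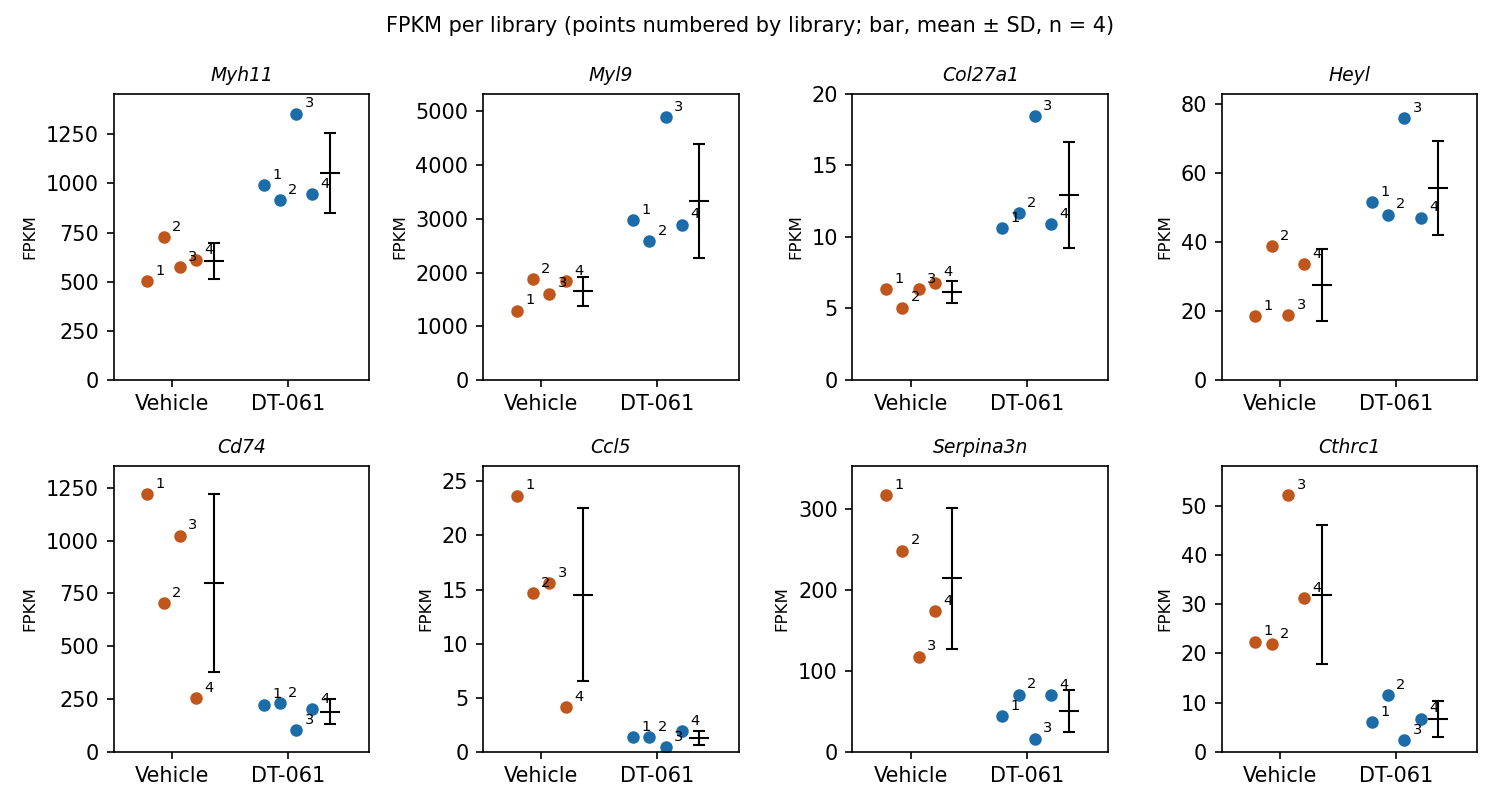
FPKM of 8 named genes in each library, with the library's number beside its point and the mean ± SD (n = 4) beside each group, on axes that start at 0. Myh11, Myl9, Col27a1 and Heyl were higher in every DT-061 library than in any vehicle library, and Cd74, Ccl5, Serpina3n and Cthrc1 were lower.

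Complement and coagulation genes in the table were also lower. All 9 complement and coagulation genes fell, also adjusted over the list alone, though the list did not pass the test of direction (Fisher's exact test, adjusted p = 0.083). With all 9 lower, no stronger lean to that side was possible. C4b was 4.15-fold lower and C3 3.02-fold lower, and C3 lost its call with the median rescaling, at a log2 change of -0.69. The haptoglobin gene Hp had 96.6 ± 76.8 FPKM with DT-061 and 634 ± 166 with vehicle (SD, n = 4), a log2 change of -3.17 ± 0.71 (limma adjusted p = 0.016). Lcn2, Wfdc21, Lrg1 and Serpina3n, also among the 10 largest falls, fell by 2.65, 2.76, 2.44 and 2.18 on the log2 scale. The complement score was 2.02 in DT-061 library 3 and 2.83 to 2.90 in the other DT-061 libraries, against 3.44 to 4.20 with vehicle. With quantile normalization, F5 and Tfpi2, not picked by the naming rule, turned to higher.

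Proliferation genes fell as a group. All 21 listed members, of 69 fixed, fell, also adjusted over the list alone (Fisher's exact test, adjusted p = 8.7e-04). In 11 of the 21 the groups did not overlap, against 78.3% of all genes in the table. Cenpa, a centromeric histone, had 3.66 ± 1.27 FPKM with DT-061 and 8.0 ± 1.79 with vehicle (SD, n = 4), a log2 change of -0.97 ± 0.24 (limma adjusted p = 0.017). Cdc20, a regulator of the anaphase-promoting complex, fell by 0.98 ± 0.28. The values were low, and with quantile normalization 15 of the 21 genes turned to higher, while none did with the median rescaling. Top2a lost its call without DT-061 library 3 or 4 or vehicle library 1 or 4 (limma adjusted p of 0.057 to 0.068), Mki67 without DT-061 library 3 (0.053), and both did so without DT-061 library 3 and vehicle library 4 together (0.12 and 0.084) and with both scalings. Cenpa and Cdc20 also lost their calls with both scalings, at log2 changes of -0.27 and -0.34 with the median rescaling and -0.28 and -0.16 with quantile normalization. Vehicle library 4 had the highest proliferation score, 2.06, against 1.21 to 1.88 in the other vehicle libraries and 0.74 to 1.16 with DT-061.

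Genes of the matrix and of fibroblasts moved both ways. Of 12 matrix protease and inhibitor genes, 3 rose, 8 fell and 1 did not pass, with the same counts adjusted over the list alone (Fisher's exact test, adjusted p = 0.85). Timp1, a tissue inhibitor of metalloproteinases, had 60.9 ± 22.5 FPKM with DT-061 and 186 ± 73.8 with vehicle (SD, n = 4), a log2 change of -1.60 ± 0.39 (limma adjusted p = 0.017), and the cathepsin gene Ctss fell by 1.96 ± 0.60. Of 9 proteoglycan and cartilage-like matrix genes, 3 rose and 6 fell, as they did adjusted over the list alone (Fisher's exact test, adjusted p = 1): the lubricin gene Prg4 was 4.54-fold lower and Cytl1 was 2.19-fold higher. Comp fell by 1.91 ± 0.51, and its vehicle libraries held 197 to 221 FPKM except library 4 at 55.7. Of 11 fibroblast markers, 2 rose and 9 fell, as they did adjusted over the list alone (Fisher's exact test, adjusted p = 0.66). In 11 of the 11 the groups did not overlap, against 78.3% of all genes in the table. Cthrc1, a secreted protein of activated fibroblasts, fell by 2.15 ± 0.42 (limma adjusted p = 0.014) and the Wnt modulator gene Sfrp4 had a log2 change of -1.48 ± 0.28. With the median rescaling, Timp1 and Sfrp4 lost their calls, at -0.75 and -0.66, and Ctsh, Ctsz, Mmp2 and Lum turned to higher, and with quantile normalization Has2 and Runx2 did, these 6 chosen after their values were seen. Among elastic fibre genes only Fbn2 and Thsd4 were in the table: Fbn2 fell and Thsd4 rose. Among collagens, Col11a1 fell and Col27a1 rose, the latter by 0.94 ± 0.18. The counts of both lists were the same adjusted over the list alone, and Fbn2 turned to higher with quantile normalization. Fbn2, Thsd4 and Col11a1 lie outside the naming rule, as do other members given because a list had 5 or fewer in the table.

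Signalling lists gave few genes. All 3 listed TGF-β and BMP genes, the BMP targets Id1, Id2 and Id4, rose, also adjusted over the list alone. Id4 had 42.0 ± 2.79 FPKM with DT-061 and 26.2 ± 4.42 with vehicle (SD, n = 4), a log2 change of 0.67 ± 0.12 (limma adjusted p = 0.013). Of 9 Wnt, Notch and Hedgehog genes, 6 rose and 3 fell, as they did adjusted over the list alone (Fisher's exact test, adjusted p = 0.11). Heyl had 55.7 ± 13.7 FPKM with DT-061 and 27.5 ± 10.4 with vehicle (SD, n = 4; limma adjusted p = 0.018), and the Hedgehog effector gene Gli1 rose by 0.71 ± 0.19. Nkd2, chosen after its values were seen, fell but turned to higher with both scalings, and Dll4 with quantile normalization. Of 5 genes of renin-angiotensin, endothelin, adrenergic and nitric oxide signalling, 3 rose, 1 fell and 1 did not pass, as adjusted over the list alone (Fisher's exact test, adjusted p = 0.089). The α1D adrenergic receptor gene Adra1d was 2.06-fold higher and Rgs4, a regulator of G protein signalling, rose by 0.72 ± 0.17. Of 6 ion channel genes, 3 rose and 3 fell, as adjusted over the list alone (Fisher's exact test, adjusted p = 0.58): the potassium channel genes Kcnma1 and Kcnmb1 rose by 0.66 and 0.55, Kcnn4 fell by 1.04 but lost its call with both scalings, at -0.34 and -0.32, and the mechanosensitive channel gene Piezo1 fell by 0.49 but turned to higher with both scalings, as Kcnj2, outside the naming rule, did with quantile normalization. Among the PP2A subunits and regulators only the scaffold subunit gene Ppp2r1a was in the table, with 93.4 ± 4.90 FPKM with DT-061 and 82.0 ± 2.49 with vehicle (SD, n = 4), a log2 change of 0.19 ± 0.07 (limma adjusted p = 0.041). It rose, also adjusted over the list alone, but its call ended without any library but DT-061 library 2, at limma adjusted p of 0.058 to 0.11, and with quantile normalization, at 0.35. Fbn1 was not analysed here.

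Most metabolic and stress genes in the table were lower, but the lists tested, which had few genes, did not pass the test of direction. Of 6 fatty acid and lipid genes, 4 fell and 1 did not pass, as adjusted over the list alone (Fisher's exact test, adjusted p = 0.80). Mlxipl, a glucose-sensing transcription factor, fell by 1.04 ± 0.28 but lost its call with both scalings, at -0.31 with the median rescaling and -0.44 with quantile normalization, and Gpam, outside the naming rule, turned to higher with the median rescaling. Of 7 glycolysis and hypoxia genes, 1 rose and 6 fell, as adjusted over the list alone (Fisher's exact test, adjusted p = 0.59). Vegfa fell by 0.66 ± 0.16 and Pfkfb4 by 0.64 ± 0.18. With the median rescaling, Vegfa, Pfkfb4 and Hk2 turned to higher, and with quantile normalization Pfkfb4, Pfkfb1 and Slc2a3 did; Hk2 and Slc2a3 lie outside the naming rule. The 4 unfolded protein response genes, Hspa5, Xbp1, Dnajb9 and Pdia6, fell, also adjusted over the list alone, with log2 changes of -0.76, -0.67, -0.66 and -0.52. All 4 were higher after the median rescaling, at 0.09, 0.17, 0.15 and 0.32, and lower with quantile normalization, where Hspa5 lost its call.

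Markers of other cells of the vessel and its surroundings were sparse. Of 5 endothelial genes, 1 rose and 4 fell, as adjusted over the list alone (Fisher's exact test, adjusted p = 1), with Aplnr at -1.41 ± 0.32 and Plvap at -0.83 ± 0.22 on the log2 scale. Plvap lost its call with the median rescaling, at -0.0053, and Aplnr with quantile normalization, at -0.52. Both adipocyte genes in the table, Cfd and Retn, fell, also adjusted over the list alone, and in both the groups did not overlap. Cfd, the adipsin gene, had 228 ± 124 FPKM with DT-061 and 815 ± 403 with vehicle (SD, n = 4), a log2 change of -1.94 ± 0.53 (limma adjusted p = 0.018). Of the 3 Schwann cell and neuron genes, Uchl1 and Hand2 rose and Tubb3 fell, also adjusted over the list alone, and Tubb3 lost its call with quantile normalization. Hand2, the only cardiomyocyte list member too, lost its call without each of DT-061 libraries 2 and 3 and vehicle libraries 1, 2 and 4, at limma adjusted p of 0.053 to 0.069. Of the skeletal muscle genes, Myl1 fell and Cacna1s did not pass, as adjusted over the list alone, and Cacna1s turned to higher with quantile normalization. Cdh1, the only mesothelial and epithelial gene, fell, but turned to higher with quantile normalization. Of the immediate early genes, Jund rose and Dusp2 fell, the clock gene Bhlhe40 fell, and Mxi1 of the mTOR, MYC and ribosome biogenesis list did not pass, each likewise adjusted over the list alone. No member of the oxidative phosphorylation, cholesterol, erythroid and platelet, or sex-linked lists was among the genes analysed.

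Other genes with large rises were Kcnc4, Optc, Wfdc1 and Ypel4, at 3.05-fold, 2.50-fold, 2.04-fold and 2.31-fold. DT-061 library 3 had the highest value of each, for Optc 56.1 FPKM against 17.0 to 20.4 in the other DT-061 libraries, so its fold rests largely on that library. Optc lost its call without vehicle library 1, 2 or 3, at limma adjusted p of 0.057, 0.050 and 0.051. Over the whole table, vehicle library 4 lay nearer to the DT-061 libraries than to the other vehicle libraries, with a root mean square log2 distance of 0.60 against 0.85. DT-061 library 3 lay 0.60 from the other DT-061 libraries, where those lay 0.21 to 0.34 from theirs. Vehicle library 1 also stood apart, at 0.74 from the other vehicle libraries, where vehicle libraries 2 and 3 lay 0.33 and 0.39 from theirs. It was left out only on its own, and limma then called 1069 genes. Without DT-061 library 3 and vehicle library 4, an alternative chosen after seeing the data, limma called 1186 genes.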

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

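The tests of depth and of combined length and GC trends for DT-061 library 3, and both tests for vehicle library 4, were chosen after the results were seen. A library is named here where its gap to the nearest of the other 3 libraries of its group, divided by the group's range, was above Dixon's critical value for groups of 4 on log2(FPKM + 1). That was so in 21 of 224 groups of named genes and list scores, where chance gives about 1 in 20, or 11.2.

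In 14 of the 21, the library was DT-061 library 3. It was highest for Adra1d (ratio 0.910), Col27a1 (0.832), Optc (0.851) and Ypel4 (0.884). It was lowest for C4b (0.942), Cd55 (0.973), Ctss (0.919), H2-Aa (0.936), H2-Ab1 (0.897), Ighm (0.835), Mpeg1 (0.860) and Tubb3 (0.832), and for the antigen presentation (0.850) and complement (0.925) scores. Over the table, 20 genes were higher in it than in the other DT-061 libraries by over 1 log2 unit and 117 were lower. A difference in depth is argued against, since its 14500000 fragments (to 3 significant digits) lie between those of the other DT-061 libraries. Its deviation followed exonic length and GC content weakly across genes, which are not independent replicates (Spearman rho 0.12 and 0.15), and these values lie between the bounds set beforehand, so a part played by such bias stays open. As the whole reason for its distance such bias is argued against, because with both trends removed the distance was 0.59, against 0.60 before and 0.34 for the next DT-061 library. A stronger response in that sample, or less immune tissue in it, was not tested and stays open.

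Vehicle library 4 was lowest for Comp (0.915) and for the proteoglycan and cartilage-like matrix score (0.973), and lay near the DT-061 libraries over the table. Its lower depth is argued against, since 12 immune cell genes with a mean FPKM of at least 10, each with about 111 fragments or more in that library, lay a median of -1.69 log2 units from the other vehicle libraries. A wrong treatment label cannot be excluded: 18 of its 18 contractile genes lay below the lowest DT-061 value, but the genes were chosen with it counted as vehicle, and every other vehicle library gives the same count, so this test decides nothing. The same choice bears on the 13 of 21 proliferation genes that were higher in it than in the other vehicle libraries. Less inflammation in that mouse, or less attached tissue in the dissected sample, may also be the source of its low immune values; neither was tested.

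The other values were those of Dnajb9 (0.903) and Lrg1 (0.831), highest in vehicle library 1, Id2 (0.835) and Kcnma1 (0.895), highest in vehicle library 2, and Hand2 (0.915), highest in vehicle library 3.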

How the results depend on the processing

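The removal of both doubted libraries and the median rescaling of list directions and of the balance of higher and lower genes, and the quantile normalization of named genes, were chosen after seeing the data, and the other alternatives before. limma called 942 (without vehicle library 3) to 1230 (without vehicle library 4) genes with 1 library left out, against 1268, and 1066 to 1287 with the pseudocount of 0.1, the FPKM minimum, array weights or no trend and robust options. The exact permutation test called 1041. Counts that moved by over 1.5 times were 603 with quantile normalization, 735 with the median rescaling, 834 with the replicate number as a block and, for genes whose groups did not overlap, 638 with that rescaling against 1041; which scaling is right was not tested. The values gave no sign that the replicate numbers pair the libraries. Only 1 of 8 correlated best with its own number, and the correlations of the deviations were 0.18, -0.11, -0.05 and -0.47. The genes were chosen on the group difference, and 1 component held 58.3% of the variance within groups. A weaker shared factor could be hidden by it, so pairing cannot be excluded. No other of the 34 splits of the libraries gave any call by limma (0, against 1268 in the real split, the 1 split of 35 with as many), but the genes were chosen on the real split, so this cannot exclude chance.

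The tests of the 7 lists past the threshold use only directions, and no gene of this selected table changed direction with libraries left out, so leaving them out does not test the lists. Among genes changed at least 2-fold, nearly all lower, only 9 lists, without the contractile and proliferation lists, had enough genes to be tested and 0 passed; the cytokine, interferon, antigen presentation, monocyte and macrophage, and T and NK cell lists, still with 0% of genes higher, had an adjusted p of 1. Over genes whose groups did not overlap, 0% of genes were higher in the complement list, now past the threshold (Fisher's exact test, adjusted p = 0.038), and in the monocyte and macrophage and T and NK cell lists, no longer past it (0.10 and 0.24), with fewer genes left. After the median rescaling, the complement and the neutrophil and mast cell lists, still at 0% higher, passed (adjusted p = 0.013 and 0.022), as the table then held more higher genes. Of 90 named genes, 7 reversed after that rescaling, at log2 changes of 0.15 (Dnajb9), 0.086 (Hspa5), 0.32 (Pdia6), 0.17 (Xbp1), 0.063 (Pfkfb4), 0.27 (Piezo1) and 0.16 (Vegfa), and 20 lost their call. That rescaling raised the log2 changes by a median of 0.68. The 7 genes had changes of -0.76 (Hspa5) to -0.49 (Piezo1) before it, so their falls were about as large as the shift itself. With quantile normalization 4 reversed, at 0.20 (Dll4 and Pfkfb1), 0.036 (Pfkfb4) and 0.016 (Piezo1), and 27 lost their call. The cause of the lost calls and of these 4 reversals was not tested. With 1 library left out, 3 to 10 named genes lost their call and none reversed; those that did were Dll4, Hand2, Ighm, Lck, Mki67, Mx1, Optc, Pfkfb3, Ppp2r1a, Rgs2, S100a8, S100a9, Top2a and Trbc2. Depth limits genes near 0: 98 genes were listed at 0 in at least 1 library.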

Other observations

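The tests of immune covariates and of a dominant clone were chosen after the results were seen, and so were the gene families below, which were picked from the table by their symbols. All 41 immunoglobulin variable genes in the table fell by limma, 20 of the heavy chain, 20 of the kappa chain and 1 of the lambda chain, with no change of direction under either scaling. The summed FPKM of the 20 heavy chain genes was 292, 140, 287 and 21.7 in vehicle libraries 1 to 4, and 0.225 to 4.71 in the DT-061 libraries. All 7 Gimap genes, GTPases of lymphocytes, fell, of which Gimap5 turned to higher with quantile normalization. All 7 Slfn genes fell, of which 3 turned to higher with that scaling. All 6 genes of the Serpina3 cluster and all 3 serum amyloid A genes fell, and stayed lower under both scalings. Tceal3, Tceal5, Bex3 and Bex4 rose, and stayed higher under both scalings. Members of these families share sequence, so their single values are uncertain.

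A single dominant plasma cell clone in the vehicle aortas is a hypothesis for the fall of the variable genes. It was argued against for the listed genes alone. In the 3 vehicle libraries richest in them no listed heavy or kappa chain gene took over 18.2% of the summed FPKM of its class. A clone with an unlisted variable gene would not be seen, so its presence cannot be decided. In vehicle library 1 the 20 listed kappa chain genes summed to 304 FPKM, against 3238 for the kappa constant gene Igkc. The lambda chain had only 1 listed gene, and variable genes outside the table were not analysed here.

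The rise of contractile genes together with the fall of immune genes may reflect, among other causes, a lower share of immune cells, a scaling effect or a change in smooth muscle cells. Scaling by the loss of abundant transcripts is argued against within the listed genes: those that were lower took 5.69% ± 1.79 of fragments with vehicle and 2.39% ± 0.409 with DT-061 (SD, n = 4), which raises all others by 0.050 on the log2 scale, against a median rise of 0.70 in the contractile genes. The listed genes that were higher took 10.5% to 13.3% of fragments in the vehicle libraries and 16.3% to 21.7% in the DT-061 libraries. How far this lowers all other genes was not estimated. A lower share of immune cells cannot be excluded: the difference of the contractile score was 0.68 ± 0.13 (SE) without and 0.31 ± 0.18 with the mean of 4 immune cell scores as a covariate, on 8 libraries. A change in smooth muscle cells, the biological reading that the treatment groups offer, stays open and was not tested. A group difference in attached tissue, raised above for vehicle library 4, was not tested either.

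A related hypothesis is that the interferon response follows the share of immune cells. The difference of the interferon score was -1.13 ± 0.36 (SE) without and 0.17 ± 0.19 with the immune covariate. Within groups the interferon score rose with the immune score, with a slope of 0.70 ± 0.09 (SE). In neither group did both scores order the libraries exactly alike. The orders differed in vehicle libraries 2 and 3, with immune scores of 3.43 and 3.44, and DT-061 libraries 1 and 2, with 1.52 and 1.64. With 8 libraries this remains undecided.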
